A study of Mus musculus with 17 samples.

How the data were processed

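RNA was measured in 17 mouse libraries of the strain C57BL/6J. The 14 tumor libraries were labelled Smarcb1-null and the 3 brain libraries wild type. Per the labels' protocols, total RNA was isolated with a miRNeasy kit, treated with DNase and made into TruSeq Stranded mRNA libraries, which select polyadenylated RNA and keep its strand. Reads were aligned with STAR 2.5.3a to the mouse build mm10, per the submitters' processing notes. The deposited files held raw counts of reads per gene, 1 file per library, without normalization. The tool that counted the reads, its strand setting and its treatment of reads that match several genes were not given in the sources used here, so genes with near-identical copies, overlapping genes and antisense partners are reported as uncertain.

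Each file listed 50600 Ensembl gene IDs, of which 45737 matched the reference annotation with their version and 50376 after the version was removed. Gene symbols came from these matches. For a gene with no counts in a group, a fold is given as at least the mean CPM of the other group over a floor of 3 counts in the summed total count of the group's libraries. Floors cover counting error only, since reads without molecular identifiers are not independent molecules.

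Groups and library numbers were taken from the labels, which name 5 groups: healthy brain (n = 3), CNS tumor of the SHH subtype (n = 3), CNS tumor of the Myc subtype (n = 4), extracranial tumor (n = 4) and syngeneic graft (n = 3). Whether libraries shared an animal, a parent tumor, a litter or a preparation day was not stated. The p-values measure only the spread between these samples. Counts of replicate libraries of every group differed by far more than sampling noise, with a chi-square per gene between 65.3 and 885.3, so no library was taken for a copy of another.

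Genes were tested with the edgeR 4.0.16 quasi-likelihood test, with a robust fit, in R 4.3.3. Counts were scaled by TMM factors and low genes were removed by the filterByExpr function at its defaults (a minimum count of 10), which left 21494 genes with 99.96% of the counts. All 17 libraries entered 1 fit with a mean per group, so that the 5 groups shared 1 estimate of the spread per gene. The 9 comparisons were contrasts between these means. The comparison of tumors with brain took the unweighted mean of the 4 tumor groups on the log2 scale, so its direction can differ from that of the arithmetic means over the 14 tumors. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, with no minimum fold. CPM values were computed from the counts and the TMM-scaled library sizes, an SE of a log2 fold change was derived from the fold change and the F statistic, and means of CPM carry the SD between libraries.

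Gene lists were tested with limma 3.58.1. There were 37 lists with 611 genes of pathways, protein complexes and cell types that a brain, a tumor or a flank graft could hold. The camera test compared each list of at least 5 measured members with all other genes, on log2 CPM from voom, with a preset correlation of 0.01 between genes and again with an estimated correlation. Its p was adjusted over the lists of a comparison. The fry test was run beside it. Its directional p-value tests whether the genes of a list move, on balance, one way, and its mixed p-value whether they change in either direction, and neither compares the list with other genes. For each list the members called over all genes and those called when adjusted over the list alone were counted.

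The comparisons, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. By that rule the text could name, per comparison, the 8 largest increases and the 8 largest decreases among called genes with at least 10 CPM in the higher group, libraries that did not overlap between the groups and an ordinary gene symbol. It could also name fixed genes (Smarcb1, Myc, Mycn, Gli1, Gli2, Ptch1, Igf2bp1, Cdkn2a and Hmga2) and up to 4 members with the smallest adjusted p of each list described. Which of the genes allowed by the rule are printed was chosen after their values were seen.

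The alternatives were RLE size factors, every gene with a count, a minimum count of 50, DESeq2 1.42.0, limma voom with quality weights, the compared groups only (or the 14 tumors as 1 group), the library number as a replicate block, sex read from Ddx3y as a covariate (Syngeneic graft 1 and 2 held Xist too), only libraries whose file numbers lay in the same series, and each library left out in turn. For 1 more alternative, chosen after seeing the data, Healthy brain 1 and SHH CNS tumor 1 were left out together because they held transcripts of other tissue. Myc CNS tumor 1 and Extracranial tumor 1 and 2, which held such transcripts too, were left out only one at a time. The edgeR and limma steps were tested on simulated counts with 50 genes changed by each of 4 fold sizes. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.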

Results

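RNA was measured in 14 tumors of a mouse model of rhabdoid tumor, a cancer of early childhood, and in 3 healthy brains. The tumor is defined by loss of Smarcb1, a core subunit of the SWI/SNF chromatin remodelling complex. By their labels the tumors were CNS tumors of the SHH subtype (n = 3), CNS tumors of the Myc subtype (n = 4), extracranial tumors (n = 4) and syngeneic grafts (n = 3). The grafts were tumors grown in the flank of mice of the same strain. Total counts per library ran from 103095016 to 130835711 in brain, 35662656 to 71390917 in SHH tumors, 18685672 to 114338058 in Myc tumors, 22491998 to 52956537 in extracranial tumors and 36951431 to 96214427 in grafts. Folds against a group with no counts of a gene are at least those over the floor of 3 counts. Means of CPM are given ± SD between libraries and log2 fold changes ± SE. Adjusted p-values of genes are from edgeR and those of lists from camera, unless another tool is named. Each of the 155 list calls was lost with an estimated correlation. Values of genes with similar copies in the genome (H2 genes, Hbb-bs, Lyz2, granzymes, Psg22, Acot5, Ccl8 and Retnla) are uncertain.

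Smarcb1 (ENSMUSG00000000902.13, on the minus strand of chromosome 10 from 75896769 to 75921617 in GRCm38), the gene named in the tumors' genotype, was lower in each of the 14 tumors than in each brain. It averaged 124 ± 6.94 CPM in brain (n = 3), 14.0 ± 16.8 in SHH tumors (n = 3), 10.45 ± 3.07 in Myc tumors (n = 4), 15.4 ± 7.31 in extracranial tumors (n = 4) and 29.0 ± 3.35 in grafts (n = 3). The highest tumor was SHH CNS tumor 1 with 33.25 CPM and the lowest SHH CNS tumor 2 with 2.515 CPM, or 107 counts. The counts cover the whole gene and do not separate transcripts with and without a deleted part.

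The first principal component held 59.2% of the variance and placed brains (-163.66 to -187.82) and SHH tumors (-96.36 to -151.42) apart from the other tumors (58.27 to 114.28). The grafts stood together on the second, which held 7.7%. The median correlation of log2 CPM across genes, which are not independent replicates, was 0.941 between brain and SHH tumors, 0.752 between brain and Myc tumors and 0.914 between Myc and extracranial tumors. All 3 brains held transcripts of brain development. The median over 10 genes of early development such as Sox4, Eomes and Dlx1 was 380.6 to 429.5 CPM, and over 10 genes of mature brain such as Pvalb, Trf and Nrgn 2.75 to 4.69 CPM. The age of the brains is not given, so differences from brain in genes of immature neurons, such as Dcx, Neurod2, Neurod6 and Tbr1, depend on a stage that is not known. Some libraries also held transcripts of other tissue. Healthy brain 1 had 1215 CPM of the pituitary hormone gene Gh, 138 of Acta1 (skeletal muscle actin) and 1392 of Col1a1 (collagen), against at most 0.1352, 3.10 and 126 in the other brains. SHH CNS tumor 1 had 4017 CPM of the myelin gene Mbp against 65.1 and 28.0 in the other SHH tumors. Myc CNS tumor 1 had 71.4 CPM of Gh and a muscle score (mean log2(CPM + 1) of the list) of 2.876, and Extracranial tumor 1 and 2 also held muscle transcripts. These genes were chosen after their values were seen.

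**Figure D1:**
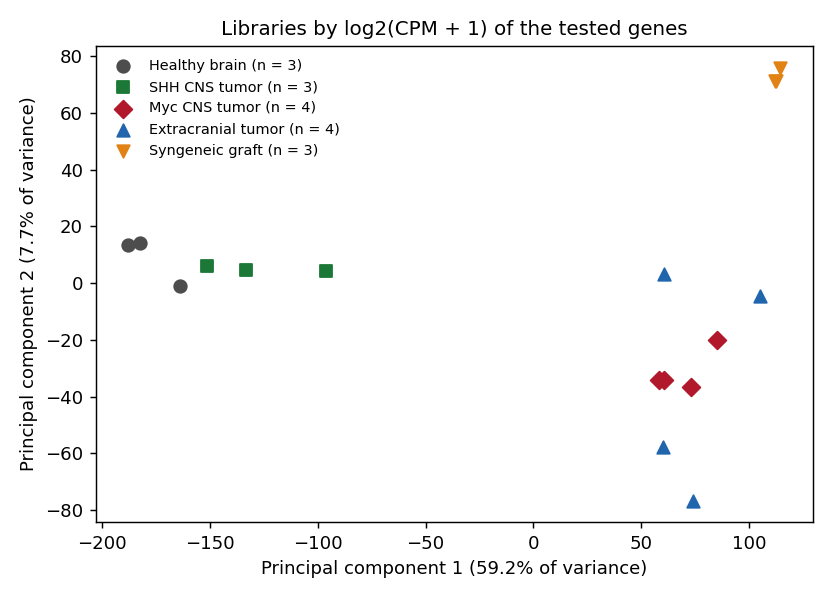
Principal components of log2 CPM of the 17 libraries, 1 point per library, with the first component (59.2% of the variance) on the x axis and the second (7.7%) on the y axis. Brains and SHH tumors lie on one side of the first component and Myc tumors, extracranial tumors and grafts on the other.

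Tumors were first compared with brain as the mean of the 4 tumor groups. The lists of antigen presentation, the interferon response, macrophages and the cell cycle were higher in tumors (n = 14) than in brain (n = 3), and those of neurons (12 of 20 genes called), astrocytes (9 of 12) and brain patterning (9 of 14 forebrain, 6 of 13 midbrain and hindbrain genes) were lower. None of these passed with an estimated correlation (adjusted p = 0.215 to 0.475). Psmb8, a subunit of the immunoproteasome, averaged 90.1 ± 79.0 CPM in tumors and 1.245 ± 0.301 in brain (log2 fold change 5.30 ± 0.33, adjusted p = 7.77e-08). Cdkn2a, which encodes inhibitors of the cell cycle, averaged 37.9 ± 29.1 and 0.0703 ± 0.0161 CPM (8.30 ± 0.56, adjusted p = 1.28e-07). Dcx, a microtubule protein of migrating neurons, averaged 13.4 ± 31.5 CPM in tumors against 1315 ± 321 in brain (-10.49 ± 0.65, adjusted p = 8.39e-08). Neurod6, a transcription factor of cortical neurons, fell as well (-10.995 ± 0.63, adjusted p = 2.67e-07).

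All measured genes of the interferon response (31, camera adjusted p = 2.39e-10), MHC class I presentation (14, adjusted p = 2.05e-08), MHC class II presentation (8, adjusted p = 0.000723) and the cell cycle (35, adjusted p = 7.85e-12) rose in tumors. Lists also rose for macrophages and monocytes (20 of 22 genes rose, adjusted p = 4.55e-07), T and NK cells (16 of 22, 0.000108), immune checkpoints (6 of 10, 0.0256), and microglia (7 of 10 rose and 1 fell, 0.0376). So did Hox genes (25 of 36, adjusted p = 1.21e-06), Myc target genes of ribosome biogenesis (29 of 46 rose and 1 fell, 1.21e-06), immediate early and heat shock genes (10 of 16, 0.000398) and cell cycle inhibitors (7 of 10 rose and 2 fell, 0.0452). With an estimated correlation T and NK cells had adjusted p = 0.317 and each of the other rising lists adjusted p = 0.288. Interferon genes included Parp14 (log2 fold change 4.67 ± 0.38), Bst2 (5.15 ± 0.59) and the RNA sensor Dhx58 (4.34 ± 0.39). B2m, the light chain of MHC class I, went from 30.65 ± 12.5 CPM in brain to 1071 ± 716 in tumors. The class II genes Cd74 and H2-Ab1 rose by 9.45 ± 1.6 and 8.885 ± 1.48. The macrophage genes Lyz2 and Itgam rose by 7.92 ± 1.03 and 5.66 ± 0.61, and Cd4 and the granzyme gene Gzmb by 4.15 ± 0.58 and 6.80 ± 1.42. Hoxc8 and Hoxc6 rose by 10.1 ± 1.15 and 9.49 ± 1.09. The replication genes Mcm3 and Cdc45 rose by 2.47 ± 0.31 and 2.43 ± 0.32, the ribosome biogenesis genes Ddx18 and Utp20 by 1.23 ± 0.16 and 1.18 ± 0.18, and Trp53 by 2.07 ± 0.23. Of the microglia markers Olfml3 rose (4.35 ± 0.50, adjusted p = 7.36e-06), while Sall1, a transcription factor of microglia and of some progenitors, fell (-3.88 ± 0.55, adjusted p = 5.21e-05). The rise of cell cycle inhibitors did not pass without Myc CNS tumor 4, Syngeneic graft 2 or Extracranial tumor 1 or 4 (adjusted p = 0.0511 to 0.058).

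Lists fell for neurons (12 of 20 genes, camera adjusted p = 7.05e-05), forebrain patterning (9 of 14, 0.000109), Notch and proneural genes (12 of 20 fell and 2 rose, 0.000907), and astrocytes (9 of 12, 0.00464). They also fell for ependyma and choroid plexus (7 of 10, adjusted p = 0.0117), midbrain and hindbrain patterning (6 of 13, 0.0215), erythroid cells (6 of 7, 0.00464) and SWI/SNF subunits (15 of 28 fell and 4 rose, 0.00472). Of these, only forebrain patterning, erythroid cells and SWI/SNF subunits were also lower as lists in SHH tumors alone. With an estimated correlation forebrain patterning had adjusted p = 0.215, astrocytes adjusted p = 0.475 and each of the other falling lists adjusted p = 0.288. The inhibitory neuron gene Slc32a1 and the neuronal nuclear protein gene Rbfox3 fell by 7.91 ± 0.64 and 5.64 ± 0.51 on the log2 scale. Tbr1, a cortical transcription factor, fell by 7.25 ± 0.49 and the globin gene Hbb-bs by 3.90 ± 0.69. Besides Smarcb1 itself (-2.96 ± 0.44, adjusted p = 7.37e-05), the SWI/SNF genes that fell included the neuronal subunits Actl6b (-8.62 ± 0.50) and Ss18l1 (-3.18 ± 0.22), and Brd9 (-1.44 ± 0.12) and Smarcc2 (-1.32 ± 0.11). Counts adjusted over the list alone were the same except for immune checkpoints (7 rose), immediate early and heat shock genes (12 rose), midbrain and hindbrain patterning (7 fell) and ependyma and choroid plexus (8 fell). The other 17 lists had camera adjusted p from 0.0668 to 0.954.

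Myc rose (1.48 ± 0.33, adjusted p = 0.00169), as did Hmga2, a chromatin protein of fetal tissue (5.72 ± 1.48, adjusted p = 0.00505). Mycn (-4.08 ± 0.44, adjusted p = 5.02e-06) fell. The Hedgehog genes Gli1 (-0.83 ± 0.61), Gli2 (-0.15 ± 1.02) and Ptch1 (-0.28 ± 0.40) and the fetal RNA-binding protein gene Igf2bp1 (0.70 ± 1.42) did not pass (adjusted p from 0.265 to 0.917). For Gli1, Gli2 and Ptch1 the arithmetic means over the 14 tumors pointed the other way (31.8, 20.1 and 111 CPM against 14.8, 11.02 and 78.4 in brain). In all, 5070 genes were higher and 6403 lower in tumors (3604 and 2848 with the 14 tumors as 1 group), and the 35 calls named here were kept without each library. With the 14 tumors as 1 group, 6 of these calls were lost, those of Myc (adjusted p = 0.0679), Actl6b (0.0874), Rbfox3 (0.0849), Sall1 (0.248), Slc32a1 (0.25) and Mycn (0.773).

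SHH tumors (n = 3) were compared with brain (n = 3), the tissue they lay closest to. As lists, genes of antigen presentation, of macrophages and of the Hedgehog pathway were higher, and genes of forebrain patterning and SWI/SNF subunits were lower. None of these passed with an estimated correlation (adjusted p = 0.347 to 0.532), and macrophages and MHC class II did not with fry (0.0998). Psmb8 averaged 5.09 ± 0.57 CPM in SHH tumors against 1.245 ± 0.301 in brain (2.03 ± 0.30, edgeR adjusted p = 0.00532). Cdkn2a averaged 2.79 ± 0.76 against 0.0703 ± 0.0161 (5.27 ± 0.52, adjusted p = 0.00084). The SWI/SNF gene Bcl7c averaged 40.7 ± 13.4 against 137 ± 11.7 (-1.75 ± 0.30, adjusted p = 0.00909). The lists that rose were Hedgehog pathway (4 of 18 rose and 1 fell, camera adjusted p = 0.000352), Hox genes (7 of 36, 1.25e-07), microglia (2 of 10, 0.0009), macrophages (6 of 22, 0.000424), MHC class I (6 of 14, 0.000183), and MHC class II (5 of 8, 0.00279). Interferon response (4 of 31, adjusted p = 0.00236), cell cycle (1 of 35, 2.22e-08) and oligodendrocytes (1 of 12, 0.0195) rose too. These had, with an estimated correlation, adjusted p = 0.347 (Hedgehog, microglia), 0.469 (Hox), 0.532 (macrophages, MHC class I and II, cell cycle) and 0.848 (interferon, oligodendrocytes). Forebrain patterning (3 of 14 fell, adjusted p = 0.00138), SWI/SNF subunits (4 of 28 fell and 1 rose, 0.0147), erythroid markers (7 of 7 not passing, 0.000352) and endothelial markers (13 of 13 not passing, 0.0147) were lower as lists. In the same order these had adjusted p = 0.347, 0.532, 0.469 and 0.675 with an estimated correlation. The neuron list did not pass (0 of 20 genes called, adjusted p = 0.336). Adjusted over the list alone, the counts were 15 for Hox genes, 6 for microglia, 13 rising and 1 falling for macrophages, 11 and 7 for MHC class I and II, 16 for interferon, 4 for the cell cycle, 8 for oligodendrocytes, 5 falling for forebrain patterning, 9 falling and 2 rising for SWI/SNF, 6 falling for erythroid markers, and the same for the other lists. Of the Hedgehog genes the receptor gene Ptch1 averaged 343 ± 131 CPM against 78.4 ± 18.4 (2.13 ± 0.54, adjusted p = 0.0411). Smo, Evc and Evc2, which act at the primary cilium, rose by 1.77 ± 0.46, 1.82 ± 0.33 and 2.03 ± 0.38. Gli1 (1.65 ± 0.85, adjusted p = 0.272) and Gli2 (2.55 ± 1.4, adjusted p = 0.309) did not pass, but were called with limma voom (2.994 and 2.499, adjusted p = 6.81e-05 and 0.000388), and Gli2 with the compared groups only (0.0393). Healthy brain 1 held 30.12 CPM of Gli1 against 7.26 and 6.98 in the other brains. Immune genes that rose included B2m (2.29 ± 0.40), Cd74 (6.23 ± 1.44), H2-Aa (6.41 ± 1.59), Itgam (3.30 ± 0.58), Lyz2 (5.02 ± 0.93) and Olfml3 (2.95 ± 0.50). Trp53 (1.31 ± 0.26), Mcm3 (1.30 ± 0.34) and Hes1, a Notch target (2.45 ± 0.48), rose as well. Among the largest increases were Msx3, a homeobox gene of the dorsal neural tube (6.92 ± 1.27), Fndc3c1 (9.45 ± 2.07), Hoxd10 (12.36 ± 2.81) and Hoxd9 (9.66 ± 2.47). The decreases were led by Neurod2 (-4.74 ± 1.13), Neurod6 (-4.44 ± 0.85), Dcx (-4.41 ± 0.96) and Tbr1 (-4.34 ± 0.80). Smarcb1 and Brd9 fell by 3.15 ± 0.72 and 0.91 ± 0.17. Mobp (11.89 ± 2.73, adjusted p = 0.029) followed SHH CNS tumor 1, which held 1371 CPM of it, and the oligodendrocyte list had adjusted p = 0.547 without that tumor. Mycn (1.45 ± 0.68, adjusted p = 0.233), Myc (-1.11 ± 0.38, 0.107), Hmga2 (1.93 ± 1.32, 0.42), Igf2bp1 (-1.88 ± 1.79, 0.573), Hbb-bs (-3.68 ± 1.17, 0.0866), Kdr (-1.35 ± 0.44, 0.0925) and Mog (8.02 ± 2.37, 0.069) did not pass. Alternatives called Mog, Hbb-bs and Kdr (DESeq2, 0.00333 to 0.0309), Mycn, Myc, Hbb-bs and Kdr (limma voom, 0.000979 to 0.0376), Kdr (compared groups only, 0.0447) and Myc (without SHH CNS tumor 2, 0.0356). edgeR called 524 genes higher and 416 lower, DESeq2 1560 and 1268, and limma voom 3274 and 4285, which turned the balance (43.3% higher against 55.7%). With 1 library left out edgeR called from 27 to 513 higher and 35 to 308 lower, with the fewest higher without Healthy brain 3. Of the 27 calls named here those of Psmb8, Cdkn2a and Bcl7c were kept without each library (12, 24 and 24 calls were lost without Healthy brain 1, 2 and 3, with adjusted p up to 0.117, 0.148 and 0.179, and 3, 6 and 20 without SHH CNS tumor 1, 2 and 3, with adjusted p up to 0.0834, 0.108 and 0.304). With the compared groups only 9 of the 27 were lost (0.0519 to 0.121), without Healthy brain 1 and SHH CNS tumor 1 together 8 (0.0603 to 0.146), with sex as a covariate 7 (0.0547 to 0.0885) and with limma voom 2 (Cd74 0.106 and H2-Aa 0.351). Of the list calls, those of the cell cycle, macrophages and MHC class II (fry adjusted p = 0.0998 each), interferon (0.417), oligodendrocytes (0.373) and endothelium (0.103) did not pass with fry. Endothelium was lost without Healthy brain 1 (0.0778) or SHH CNS tumor 2 (0.0834), and SWI/SNF without SHH CNS tumor 1 (0.153) or Healthy brain 2 (0.0554).

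Myc tumors (n = 4) were compared with brain (n = 3). Myc itself, Prrx1 and Twist1 were higher in Myc tumors. So were the lists of macrophages and the interferon response, while those of neurons (10 of 20 genes called) and Notch and proneural genes (14 of 20 fell and 2 rose) were lower, but not with an estimated correlation (adjusted p = 0.337 to 0.378). Myc averaged 127 ± 29.2 CPM against 26.4 ± 5.36 in brain (2.27 ± 0.38, edgeR adjusted p = 0.000268), and Mycn 0.310 ± 0.154 against 44.2 ± 13.9 (-7.085 ± 0.78, adjusted p = 1.28e-05). Prrx1 and Twist1, transcription factors of the mesenchyme, rose by 5.54 ± 0.94 and 5.82 ± 1.17, to 789 ± 489.5 and 129 ± 47.2 CPM. Their list of mesenchymal and neural crest factors did not pass (4 of 20 rose and 3 fell, or 3 and 2 adjusted over the list alone, camera adjusted p = 0.721, 0.873 with an estimated correlation). Hmga2 averaged 544 ± 178 CPM in Myc tumors and 2.35 ± 0.55 in brain (7.85 ± 1.70, adjusted p = 0.00172), and Cdkn2a rose by 9.53 ± 0.60 (adjusted p = 6.52e-07).

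The interferon response (31 of 31 genes rose, camera adjusted p = 4.84e-12), MHC class I (14 of 14, 5e-09), MHC class II (8 of 8, 0.00169), macrophages (20 of 22, 2.09e-07) and T and NK cells (14 of 22, 0.00222) rose as lists. The cell cycle (32 of 35, adjusted p = 3.08e-10), Myc target genes of ribosome biogenesis (31 of 46, 9.53e-08), Hox genes (25 of 36, 2.84e-06) and immediate early and heat shock genes (12 of 16, 4.12e-05) rose too. These lists had adjusted p = 0.337 (MHC class I, macrophages, immediate early genes), 0.48 (T and NK cells) and 0.36 (the others) with an estimated correlation. Notch and proneural genes (14 of 20 fell and 2 rose, adjusted p = 0.00057), neurons (10 of 20, 0.000701), forebrain patterning (6 of 14, 0.000761) and SWI/SNF subunits (16 of 28 fell and 4 rose, 0.00155) fell. So did erythroid cells (6 of 7, adjusted p = 0.00739), ependyma and choroid plexus (7 of 10, 0.0226) and midbrain and hindbrain patterning (6 of 13, 0.0274). The falling lists had, with an estimated correlation, adjusted p = 0.337 (Notch and proneural, forebrain, SWI/SNF), 0.378 (neurons), 0.36 (erythroid, ependyma) and 0.355 (midbrain and hindbrain). Adjusted over the list alone, the counts were 33 for the cell cycle, 32 for Myc targets, 13 for immediate early genes, 12 for neurons and 8 for ependyma, and the same for the other lists. Parp14 and Bst2 rose by 5.18 ± 0.41 and 6.4 ± 0.65 and B2m and Psmb8 by 4.965 ± 0.45 and 5.73 ± 0.35. Lyz2 and Itgam rose by 8.15 ± 1.07 and 5.97 ± 0.64 and Hoxc8 and Hoxc6 by 12.66 ± 1.26 and 11.05 ± 1.17. Ddx18 rose by 1.56 ± 0.19 and Mcm3 by 2.55 ± 0.34. Dcx and Sox11, genes of immature neurons, fell by 11.95 ± 1.15 and 8.56 ± 1.18. Rbfox3 and the glutamate receptor gene Grin1 fell by 6.75 ± 0.87 and 6.28 ± 0.83. Hes5, a Notch target, had no counts in the 4 Myc tumors and 11.8 ± 4.67 CPM in brain, at least 879-fold lower.

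Collagen gene Col5a2 (4.26 ± 0.87, adjusted p = 0.00112) and the growth factor receptor gene Pdgfra (3.17 ± 0.80, adjusted p = 0.0046) were among the 5 of 22 fibroblast and extracellular matrix genes that rose (camera adjusted p = 0.0932). Among imprinted and fetal genes Hmga1 rose (3.11 ± 0.61) and Peg3 fell (-4.55 ± 0.54). The largest increases included Gata4, a transcription factor of endoderm and heart (63.5 ± 99.1 against 0.0118 ± 0.0066 CPM, adjusted p = 0.00403), and Psg22, a pregnancy-specific glycoprotein gene (101 ± 121 CPM, no counts in brain, adjusted p = 0.0145). Both were highest in Myc CNS tumor 2 and 4. Smarcb1 fell (-3.57 ± 0.65, adjusted p = 0.000532). Gli1 (-1.38 ± 0.77), Gli2 (-1.36 ± 1.24) and Igf2bp1 (2.06 ± 1.73) did not pass (adjusted p from 0.146 to 0.372), though Gli2 was called with limma voom (-2.145, 0.042) and without Myc CNS tumor 1 (-3.293, 0.0436). Ptch1 fell from 78.4 ± 18.4 to 26.8 ± 3.545 CPM (-1.55 ± 0.48, adjusted p = 0.0156, 0.0507 without Healthy brain 1). The other 28 calls named here were kept without each library. In all, 5445 genes were higher and 5771 lower. Of the lists, midbrain and hindbrain patterning did not pass without Healthy brain 2 (0.0588) or Myc CNS tumor 3 (0.0514).

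Extracranial tumors (n = 4) were compared with brain (n = 3), a tissue they did not arise in. Myc and the lists of matrix genes (11 of 22 called), Hox genes (17 of 36), macrophages and the interferon response were higher in the tumors, and those of neurons (13 of 20), astrocytes (10 of 12) and forebrain patterning (8 of 14) were lower. No list passed with an estimated correlation (adjusted p = 0.307 to 0.43 for these). Col5a2 averaged 2152 ± 1266 CPM against 98.15 ± 80.3 (4.455 ± 0.87, edgeR adjusted p = 0.000853), and Hoxc8 66.75 ± 43.4 against 0.00588 ± 0.00517 (13.085 ± 1.27, adjusted p = 5.24e-06). Neurod6, with 147 ± 86.6 CPM in brain, had no counts in the 4 tumors. Myc rose by 2.36 ± 0.38 (adjusted p = 0.000197). Gli1, a Hedgehog target, averaged 70.4 ± 38.5 CPM against 14.8 ± 13.3 (2.25 ± 0.83, adjusted p = 0.0349).

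The lists that rose were interferon response (31 of 31 genes, camera adjusted p = 1.03e-10), MHC class I (14 of 14, 3.68e-09), MHC class II (8 of 8, 0.000445), macrophages (20 of 22, 8.46e-08), T and NK cells (17 of 22 rose and 1 fell, 0.000839), immune checkpoints (5 of 10, 0.0339) and microglia (7 of 10 rose and 1 fell, 0.0393). So did cell cycle (35 of 35, adjusted p = 1.03e-10), cell cycle inhibitors (7 of 10 rose and 1 fell, 0.0322), Myc target genes of ribosome biogenesis (31 of 46 rose and 1 fell, 4.25e-06) and Hox genes (17 of 36, 0.000577). Fibroblast and extracellular matrix genes (11 of 22, adjusted p = 0.0127), immediate early and heat shock genes (13 of 16, 7.89e-05) and mitochondrially encoded genes (4 of 13, 0.04) also rose. For T and NK cells adjusted p = 0.416 with an estimated correlation, for Hox genes 0.383, for matrix genes 0.348, for mitochondrial genes 0.633 and for each of the others adjusted p = 0.307. Neurons (13 of 20 fell, adjusted p = 0.000101), forebrain patterning (8 of 14, 0.000457), Notch and proneural genes (12 of 20 fell and 2 rose, 0.000457), and astrocytes (10 of 12, 0.00406) fell. Erythroid cells (7 of 7, adjusted p = 0.0048), SWI/SNF subunits (14 of 28 fell and 4 rose, 0.00514), midbrain and hindbrain patterning (6 of 13, 0.0109) and ependyma and choroid plexus (6 of 10, 0.0109) fell too. Astrocytes had adjusted p = 0.43 with an estimated correlation and each of the other falling lists adjusted p = 0.307. Counted by p adjusted over the list alone, 8 microglia genes rose, 14 neuron genes and 2 cell cycle inhibitors fell, and the other counts were the same. Psmb8, Dhx58 and Cd74 rose by 5.96 ± 0.35, 5.72 ± 0.44 and 10.255 ± 1.68. The chemokine gene Cxcl9, between 0.102 and 376.8 CPM in the 4 tumors, rose by 12.14 ± 2.56. The matrix genes Fbln2 and Dcn rose by 4.88 ± 1.35 and 5.21 ± 1.48, Prrx1 by 5.395 ± 0.93 and Evc by 2.83 ± 0.33. Hoxc9 averaged 16.03 ± 10.4 CPM and had no counts in brain, at least 1929-fold higher. The synaptic gene Syp (-7.04 ± 0.96), Slc32a1 (-11.74 ± 1.26), Dcx (-12.72 ± 1.19), Peg3 (-5.25 ± 0.55) and Lin28b, a fetal RNA-binding protein gene (-9.52 ± 1.34), fell. Olig1, a transcription factor of the oligodendrocyte lineage, was at least 2294-fold lower, with no counts in the 4 tumors. The choroid plexus gene Ttr had none in the tumors either, and 352.7 ± 354 CPM in brain (0.9385 in Healthy brain 3).

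Cdkn2a rose (8.59 ± 0.58, adjusted p = 8.84e-07), and Mycn (-4.94 ± 0.70, adjusted p = 7.79e-05) and Smarcb1 (-3.01 ± 0.64, adjusted p = 0.00148) fell. Ptch1 (0.18 ± 0.49), Gli2 (0.54 ± 1.25) and Igf2bp1 (0.50 ± 1.63) did not pass (adjusted p from 0.737 to 0.814), though Igf2bp1 fell (-3.823, 0.0403) without Extracranial tumor 3. Hmga2 rose (5.88 ± 1.55, adjusted p = 0.00595), with values from 1.10 to 383 CPM between the extracranial tumors. edgeR called 5610 genes higher and 5620 lower. Of the 25 calls named in this comparison 24 were kept without each library, the exception being Gli1 (adjusted p = 0.121 and 0.124 without Healthy brain 2 and 3, 0.0608 and 0.0756 without Extracranial tumor 1 and 3). Hmga2 (0.0557) and Dcn (0.058) did not pass with the compared groups only and Ttr (0.233) did not with limma voom. Of the list calls, immune checkpoints were lost without Extracranial tumor 3 (0.0501), microglia without Healthy brain 1 (0.0508), and mitochondrial genes with RLE factors (0.0537) and without Healthy brain 1 (0.111), Extracranial tumor 3 (0.0909) or Extracranial tumor 4 (0.174).

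**Figure D2:**
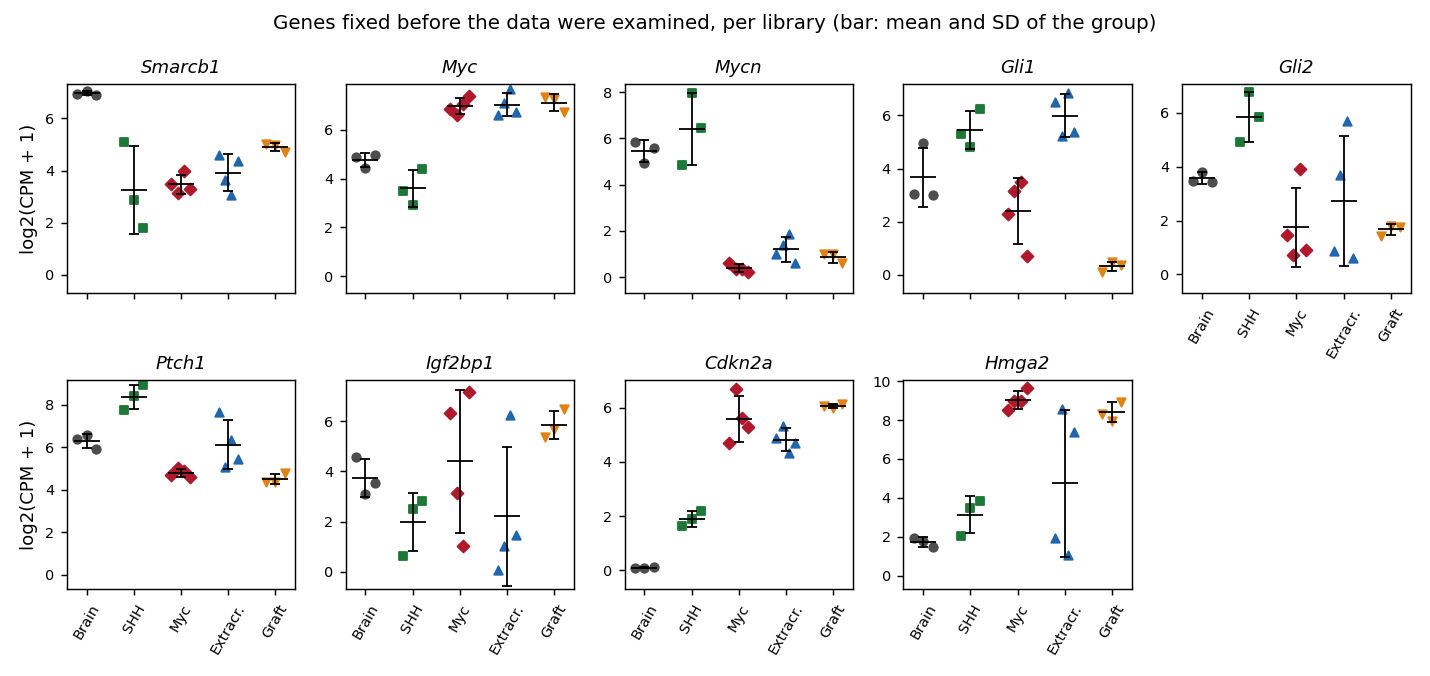
Values of 9 fixed genes as log2(CPM + 1), 1 point per library and 1 panel per gene, with the group mean and SD as bars. Smarcb1 is lower in each of the 14 tumors than in each of the 3 brains, and Hmga2 and Igf2bp1 differ widely among the 4 extracranial tumors.

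Syngeneic grafts (n = 3) were compared with brain (n = 3). Among the lists, T and NK cells, macrophages, antigen presentation and the cell cycle were higher in the grafts and neurons (14 of 20 genes called) were lower, which did not pass with an estimated correlation (adjusted p = 0.253 to 0.331). Psmb8 averaged 223 ± 22.5 CPM against 1.245 ± 0.301 (7.48 ± 0.38, edgeR adjusted p = 8.91e-08), and Cd4 40.8 ± 8.54 against 0.343 ± 0.0716 (6.885 ± 0.70, adjusted p = 6.15e-06). Ccl8, a chemokine gene of macrophages, averaged 731 ± 261 CPM against 0.0559 ± 0.0209 (13.62 ± 1.72, adjusted p = 2.9e-05). Mcm3 averaged 185 ± 7.999 CPM against 15.7 ± 1.91 (3.55 ± 0.37, adjusted p = 6.77e-06). The median log2 fold change of all genes was -0.16 here, -0.13 for grafts against extracranial tumors and -0.11 for grafts against Myc tumors.

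All 31 interferon response genes (camera adjusted p = 1.47e-13), all 14 of MHC class I (5.83e-10), all 8 of MHC class II (0.000111) and all 35 of the cell cycle (4.21e-14) rose. T and NK cells (20 of 22 genes rose, adjusted p = 1.08e-09), macrophages (20 of 22, 2.14e-09), immune checkpoints (7 of 10 rose and 1 fell, 0.00482) and microglia (7 of 10 rose and 1 fell, 0.0424) rose too. So did Hox genes (24 of 36, adjusted p = 1.51e-08), Myc target genes of ribosome biogenesis (31 of 46, 3.61e-07), immediate early and heat shock genes (9 of 16, 0.00121) and cell cycle inhibitors (7 of 10 rose and 1 fell, 0.0302). Microglia had adjusted p = 0.317 with an estimated correlation, immediate early genes 0.262 and each of the others adjusted p = 0.253. Neurons (14 of 20, adjusted p = 0.000325), forebrain patterning (11 of 14, 0.00198), Notch and proneural genes (12 of 20 fell and 2 rose, 0.00441) and astrocytes (11 of 12, 0.00557) fell. SWI/SNF subunits (14 of 28 fell and 4 rose, adjusted p = 0.00962), ependyma and choroid plexus (7 of 10, 0.0222), keratinocytes (7 of 9 fell and 1 rose, 0.0295) and midbrain and hindbrain patterning (7 of 13, 0.048) fell too. Each of these lists had, with an estimated correlation, adjusted p = 0.253 or higher, with 0.331 for neurons, 0.491 for astrocytes and 0.334 for ependyma. When adjusted over the list alone, all 22 T and NK cell genes and 33 Myc targets rose, 8 keratinocyte genes and 2 cell cycle inhibitors fell, and the other counts were the same. Cd3d, Gzmb and Klrk1, genes of T and NK cells, averaged 8.76 ± 4.13, 45.3 ± 12.3 and 37.6 ± 8.46 CPM in grafts. Klrk1 had no counts in brain (at least 4525-fold higher). The class II genes Ciita and H2-Ab1 rose by 9.915 ± 1.41 and 11.65 ± 1.68 and Parp14 and Cxcl9 by 6.75 ± 0.45 and 13.09 ± 2.64. The macrophage genes Fcer1g and Retnla rose by 6.66 ± 0.64 and 13.535 ± 2.465 and Cdc45 by 3.28 ± 0.37. Of the endothelial markers 4 of 13 rose (camera adjusted p = 0.0533), among them Emcn (2.51 ± 0.45) and Cdh5 (1.77 ± 0.51). Dcx (-12.86 ± 1.365) and Slc32a1 (-12.05 ± 1.43) fell.

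Gli1 (-5.855 ± 1.03, adjusted p = 0.000355), Ptch1 (-1.86 ± 0.53, adjusted p = 0.00917) and Sfrp1 (-7.365 ± 0.83, adjusted p = 1.27e-05), of the Hedgehog list, fell. Gli2 (-2.32 ± 1.395, adjusted p = 0.17, but 0.00535 with limma voom and 0.00046 with the compared groups only) did not pass. Myc (2.405 ± 0.39), Hmga2 (7.22 ± 1.67) and Cdkn2a (9.82 ± 0.615) rose and Mycn (-5.76 ± 0.83) fell (adjusted p from 4.17e-07 to 0.00241). Igf2bp1 did not pass (2.11 ± 1.80, adjusted p = 0.332, but 0.00237 with limma voom and 0.00754 with the compared groups only). Smarcb1 fell by 2.10 ± 0.69 (adjusted p = 0.0186, 0.0606 without Syngeneic graft 3). The other 25 calls named here were kept without each library. edgeR called 5349 genes higher and 6542 lower. Of the lists, keratinocytes were lost without Healthy brain 1 (0.0711), microglia without Healthy brain 2 (0.0509) or Syngeneic graft 3 (0.0523), and midbrain and hindbrain patterning with RLE factors (0.0545) and without Healthy brain 2 (0.0678) or Syngeneic graft 3 (0.0962).

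Myc tumors (n = 4) were compared with SHH tumors (n = 3) to set the CNS subtypes against each other. The Hedgehog genes Ptch1, Gli1 and Shh were lower in Myc tumors, as were the lists of neurons (11 of 20 genes called) and Notch and proneural genes (14 of 20). Macrophages, the interferon response, matrix genes (10 of 22) and Myc target genes (30 of 46) were higher as lists. With an estimated correlation none of these lists passed (adjusted p = 0.16 to 0.473). Myc averaged 127 ± 29.2 CPM in Myc tumors and 12.3 ± 6.97 in SHH tumors (3.37 ± 0.40, edgeR adjusted p = 6.12e-05). Mycn averaged 0.310 ± 0.154 and 121 ± 115 (-8.53 ± 0.83, adjusted p = 1.96e-05). Ptch1 averaged 26.8 ± 3.54 and 343 ± 131 CPM (-3.68 ± 0.51, adjusted p = 0.000166). Otx2, a transcription factor of the anterior neural plate, averaged 0.0314 ± 0.0241 and 128.5 ± 61.2 CPM (-11.87 ± 1.6, adjusted p = 0.000141).

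Higher in Myc tumors were the lists of interferon response (29 of 31 genes rose, camera adjusted p = 1.68e-12), MHC class I (14 of 14, 5.57e-09), MHC class II (4 of 8, 0.0366), macrophages (21 of 22, 2.21e-06), T and NK cells (12 of 22, 0.000729) and neutrophils (7 of 10, 0.00758). So were Myc target genes of ribosome biogenesis (30 of 46, adjusted p = 3.64e-09), cell cycle (11 of 35, 1.82e-05), immediate early and heat shock genes (12 of 16, 3.89e-05). Fibroblast and extracellular matrix genes (10 of 22, adjusted p = 0.00689), Hox genes (9 of 36 rose and 1 fell, 0.0366) and endothelium (3 of 13, 0.0366) were higher too. The higher lists had adjusted p = 0.609 (MHC class II, cell cycle, endothelium), 0.659 (Hox), 0.558 (T and NK cells), 0.436 (matrix) and 0.308 (the others) with an estimated correlation. Lower were Notch and proneural genes (14 of 20 fell, adjusted p = 2.08e-07), neurons (11 of 20, 0.000139), SWI/SNF subunits (12 of 28 fell and 2 rose, 0.00758) and midbrain and hindbrain patterning (5 of 13, 0.0175). Astrocytes (7 of 12, adjusted p = 0.0177), forebrain patterning (3 of 14, 0.0408) and ependyma and choroid plexus (8 of 10, 0.0408) were lower too. The lower lists had, with an estimated correlation, adjusted p = 0.16 (Notch and proneural), 0.473 (neurons), 0.609 (astrocytes), 0.558 (ependyma) and 0.308 (the others). Adjusted over the list alone, the counts were 31 for interferon, 7 for MHC class II, 22 for macrophages, 13 for T and NK cells, 33 for Myc targets, 10 for the cell cycle, 13 for immediate early genes, 11 for matrix genes, 1 for endothelium, 14 for neurons, 8 for astrocytes and 9 for ependyma, and the same for the other lists. Psmb8, B2m, Parp14, Dhx58 and Bst2 rose by 3.70 ± 0.31, 2.68 ± 0.40, 3.87 ± 0.38, 4 ± 0.40 and 4.83 ± 0.605. The macrophage receptor gene Mrc1 rose by 5.42 ± 1.025 and Gzmb and Gzmc by 8.655 ± 1.59 and 11.705 ± 2.23. Col5a2 and Col1a2 rose by 4.98 ± 0.90 and 5.47 ± 1.26 and Hoxc8 and Hoxc6 by 8.29 ± 1.025 and 6.69 ± 0.94. Ddx18 rose by 1.215 ± 0.185 and Mcm6 by 1.37 ± 0.29. Neurog2 (-8.905 ± 1.18), Sox1 (-9.95 ± 0.94), Dcx (-7.54 ± 0.99), Grin1 (-6.53 ± 0.84), Rbfox3 (-5.63 ± 0.83), En2 (-8.79 ± 1.37), Actl6b (-7.12 ± 0.78) and Smarcc2 (-1.02 ± 0.15) fell. Hes5, at 36.2 ± 20.9 CPM in SHH tumors, had no counts in Myc tumors (at least 2704-fold lower). Mobp (463 ± 786 CPM in SHH tumors, adjusted p = 0.0194) was called lower. It had adjusted p = 0.834 without SHH CNS tumor 1, which held 1371 CPM of it.

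Of 18 Hedgehog genes 8 fell and 3 rose, also when adjusted over the list alone. Camera did not pass (adjusted p = 0.0685), but fry did (lower, 0.00189). Shh (-5.31 ± 1.21), Gli1 (-3.04 ± 0.80) and Gli2 (-3.91 ± 1.33, adjusted p = 0.03) fell. Cdkn2a (4.26 ± 0.47) and Hmga2 (5.92 ± 1.55) rose. Gata4 and Psg22 had no counts in SHH tumors (at least 3034-fold and 4830-fold higher in Myc tumors). Smarcb1 (-0.42 ± 0.62, adjusted p = 0.605, but 1.364 and 0.0453 with limma voom) and Igf2bp1 (3.95 ± 1.91, adjusted p = 0.11, but 0.0229 with DESeq2) did not pass. edgeR called 4087 genes higher and 4702 lower. Of the 35 calls named here 32 were kept without each library, the exceptions being Mobp, Gli2 (adjusted p = 0.0503 to 0.0823 without SHH CNS tumor 2 or 3 or Myc CNS tumor 2, 3 or 4) and Psg22 (0.0539 to 0.0566 without any 1 SHH tumor). Psg22 (0.0524) and Mobp (0.103) were also lost with the compared groups only. Of the list calls, fry did not pass for Hox genes (adjusted p = 0.143), MHC class II (0.0683) and endothelium (0.0818). With 1 library left out the adjusted p reached 0.0526 for astrocytes, 0.114 for endothelium, 0.279 for ependyma (without SHH CNS tumor 1), 0.114 for forebrain patterning, 0.122 for Hox genes and 0.0836 for MHC class II, with 0.0536 for ependyma and forebrain patterning under RLE factors.

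Extracranial tumors (n = 4) were compared with Myc tumors (n = 4), which carried similar levels of Myc (135 ± 47.0 and 127 ± 29.2 CPM, 0.09 ± 0.32, edgeR adjusted p = 0.93). edgeR called 4 genes, each lower in extracranial tumors. Pcsk1n, which encodes an inhibitor of a prohormone convertase, averaged 0.0403 ± 0.0410 CPM against 14.4 ± 12.8 in Myc tumors (-8.74 ± 1.19, adjusted p = 0.0328), and Ttc39a 0.612 ± 0.257 against 15.7 ± 13.3 (-4.665 ± 0.67, adjusted p = 0.0328). The others were Ttc39aos1 (-5.51 ± 0.73, adjusted p = 0.0328) and the predicted gene Gm42141 (-4.99 ± 0.72, adjusted p = 0.0328), both named after their values were seen. Ttc39aos1 is the antisense partner of Ttc39a, and since the strand setting of the counting is unknown, their reads may not have been separated.

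Genes with large differences that did not pass included the astrocyte genes Gfap (0.259 ± 0.0281 against 82.95 ± 128 CPM, -8.33 ± 1.48, adjusted p = 0.0679) and Aqp4 (-10.24 ± 2.30, adjusted p = 0.101) and the endothelial tight junction gene Cldn5 (-3.54 ± 0.685, adjusted p = 0.0771). The progenitor gene Sox2 (-5.91 ± 1.18, adjusted p = 0.0771) and Hoxd13 (-7.035 ± 1.86, adjusted p = 0.133) did not pass either. Gli1 (3.63 ± 0.79, adjusted p = 0.0935), Ptch1 (1.73 ± 0.46, 0.135), the matrix genes Col6a3 (4.15 ± 0.945, 0.104) and Postn (5.37 ± 1.37, 0.131), Cd4 (1.98 ± 0.49, 0.125) and Csf1r (1.20 ± 0.45, 0.222) had positive values and did not pass. The other fixed genes were Mycn (2.145 ± 0.64), Gli2 (1.905 ± 1.19), Smarcb1 (0.56 ± 0.58), Cdkn2a (-0.935 ± 0.36), Hmga2 (-1.97 ± 1.14) and Igf2bp1 (-1.56 ± 1.53), with adjusted p from 0.156 to 0.677. DESeq2 called Gfap, Aqp4, Cldn5, Sox2, Hoxd13, Gli1, Ptch1, Col6a3, Postn, Cd4 and Mycn (adjusted p from 5.32e-12 to 0.0291), and edgeR called Gfap and Cldn5 without Myc CNS tumor 1 (0.0339 and 0.0368) and Gfap and Sox2 without Myc CNS tumor 2 (0.0132 each).

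As lists, mitochondrially encoded genes (camera adjusted p = 0.000158), skeletal muscle (0.00252) and MHC class II (0.00332) were higher in extracranial tumors, with adjusted p = 0.753 each with an estimated correlation. Astrocytes (adjusted p = 0.00154), Hox genes (0.00467), simple epithelium (0.00467), imprinted and fetal genes (0.0176), neurons (0.034), interferon response (0.02), oligodendrocytes (0.0436) and Myc target genes of ribosome biogenesis (0.0437) were lower. These had adjusted p = 0.753 with an estimated correlation, or 0.754 for interferon, oligodendrocytes and Myc targets. No member of these 11 lists was called by edgeR, and no list passed with fry (adjusted p from 0.495 to 0.632). When adjusted over the list alone, 4 astrocyte genes, 3 imprinted and fetal genes, 3 epithelial genes and 2 neuron genes fell and 1 epithelial gene rose. The interferon list had a median log2 fold change of -0.05 and a mean of 0.056, and was called lower.

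edgeR called 0 genes higher and 4 lower, with 3387 genes at raw p below 0.05, where DESeq2 called 478 and 745 and limma voom 0 and 0. With 1 library left out the counts ranged from 0 to 23 and 0 to 71. None of the 4 calls was kept without each library (adjusted p from 0.0568 to 0.0604 without Extracranial tumor 1, 0.0516 to 0.0621 for Pcsk1n, Ttc39a and Gm42141 without tumor 3, and 0.0978 to 0.156 without tumor 4), nor was any with the compared groups only (0.168 to 0.536) or limma voom (0.155 to 0.464). Of the lists, astrocytes and mitochondrial genes were kept without each library. The other 9 were each lost without 1 or more libraries, with adjusted p up to 0.513 (Hox genes without Extracranial tumor 2).

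**Figure D3:**
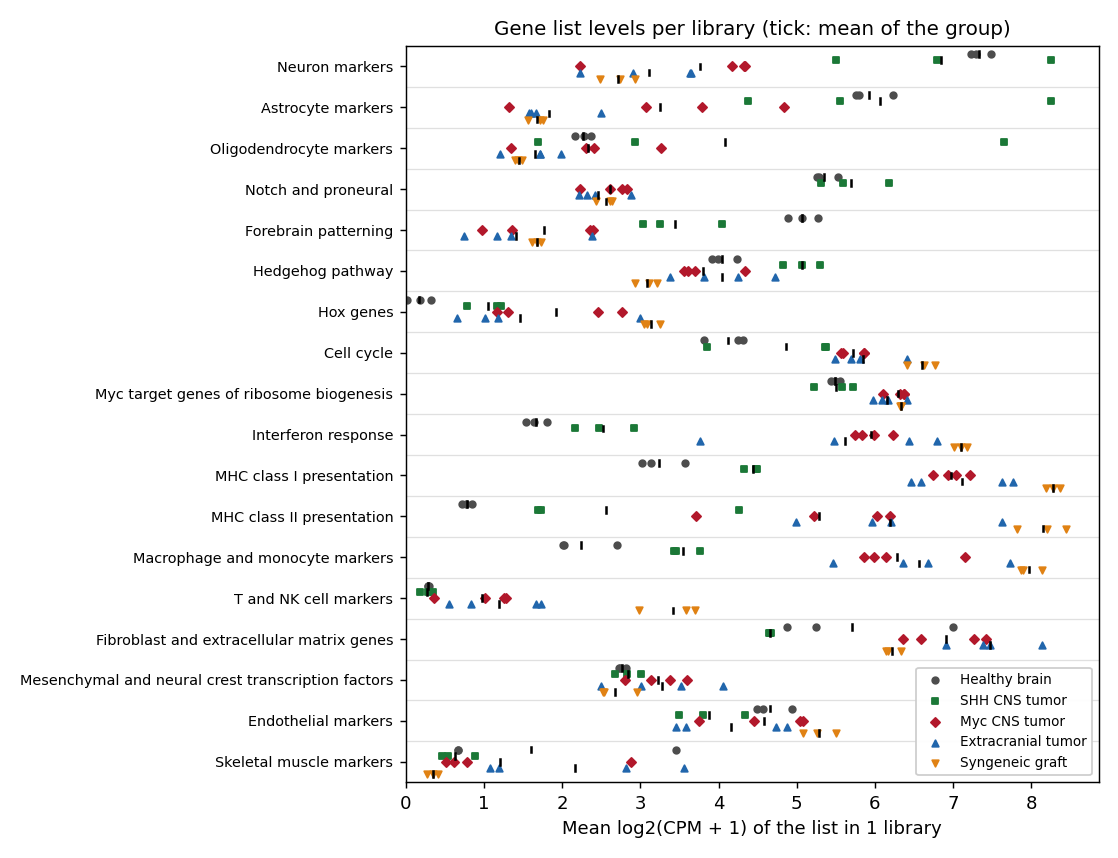
Mean log2(CPM + 1) of the genes of 18 lists in each library, 1 point per library, with a tick at the group mean. T and NK cell and MHC class II genes are highest in the grafts, and neuronal genes in brain and SHH tumors.

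Syngeneic grafts (n = 3) were compared with extracranial tumors (n = 4), which had similar levels of Myc (140 ± 31.5 and 135 ± 47.0 CPM, 0.05 ± 0.35, edgeR adjusted p = 0.959). T and NK cell (6 of 22 called) and MHC class I genes (2 of 14) were higher in the grafts as lists, but not with an estimated correlation (adjusted p = 0.213 and 0.23). The Hedgehog genes Gli1 and Ptch1 were lower. Gli1 averaged 0.248 ± 0.153 CPM in grafts and 70.4 ± 38.5 in extracranial tumors (-8.11 ± 1.13, adjusted p = 0.00481). Pcsk1n averaged 77.8 ± 26.7 and 0.0403 ± 0.0410 CPM (11.18 ± 1.27, adjusted p = 0.00261). The acyl-CoA thioesterase gene Acot5 (at least 1414-fold higher, adjusted p = 0.00773) and the interferon gamma gene Ifng (at least 29.18-fold higher, adjusted p = 0.00903) had no counts in extracranial tumors. Pdcd1lg2, which encodes a ligand of PD-1, rose by 5.98 ± 0.94 (adjusted p = 0.00903).

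T and NK cells (6 of 22 genes rose, camera adjusted p = 4.74e-18), immune checkpoints (2 of 10, 0.00339), MHC class I (2 of 14, 2.75e-09), interferon response (2 of 31, 8.95e-13), Hox genes (2 of 36, 5.72e-08), endothelium (1 of 13, 2.13e-06) and erythroid cells (1 of 7, 0.000412) were higher as lists. With no member passing, macrophages (22, adjusted p = 5.2e-08), MHC class II (8, 2.83e-05), the cell cycle (35, 9.1e-11), Myc target genes (46, 0.0298) and imprinted and fetal genes (18, 0.0441) were higher too. For T and NK cells adjusted p = 0.213 with an estimated correlation, for checkpoints and MHC class I 0.23, for the cell cycle 0.388, for Myc targets 0.769 and for the others 0.273. Mitochondrially encoded genes (3 of 13 fell, adjusted p = 4.7e-07), skeletal muscle (1 of 15, 0.000208), the Hedgehog pathway (3 of 18, 0.00598), keratinocytes (9 of 9 not passing, 0.0108) and matrix genes (3 of 22, 0.0192) were lower. The lower lists had adjusted p = 0.273 (mitochondrial, Hedgehog), 0.43 (muscle), 0.213 (keratinocytes) and 0.446 (matrix) with an estimated correlation. In counts adjusted over the list alone, 15 T and NK cell genes, 6 of MHC class I, 3 of MHC class II, 7 interferon, 5 endothelial and 6 erythroid genes rose. On the same basis 5 checkpoint genes rose and 2 fell, 6 Hox genes rose and 1 fell, and 10 mitochondrial, 9 muscle, 8 Hedgehog, 6 matrix and 3 keratinocyte genes fell.

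Gzmb and Lck, genes of cytotoxic cells and T cell signaling, rose by 5.05 ± 1.11 and 2.54 ± 0.59, and the checkpoint receptor gene Tigit by 3.91 ± 0.95. Psmb8, the peptide transporter gene Tap1 and Parp14 rose by 1.52 ± 0.27, 1.45 ± 0.29 and 1.29 ± 0.32. Hoxd13, a gene of the posterior body axis, averaged 83.3 ± 33.1 against 0.0927 ± 0.0928 CPM, and the transcription cofactor gene Cited1 524 ± 46.1 against 1.08 ± 1.19. Emcn rose by 1.497 ± 0.395, and the erythroid gene Slc4a1 had no counts in extracranial tumors (at least 13.32-fold higher). Ptch1 and Sfrp1 fell by 2.04 ± 0.52 and 3.165 ± 0.675. Col5a2 and Fbln2 fell by 4.145 ± 0.86 and 6.57 ± 1.47, the muscle gene Actn3 by 4.63 ± 0.98 and Bmp4 by 4.50 ± 1.09. The muscle score was 3.552, 2.817, 1.195 and 1.075 in Extracranial tumor 1 to 4. Among the largest decreases were Aqp5, a water channel gene (-15.43 ± 2.84), and Grem1, which encodes an antagonist of BMP signaling (-13.33 ± 2.71). Cdkn2a (1.23 ± 0.39, adjusted p = 0.0725), Mcm3 (1.07 ± 0.31, 0.0593), Adgre1 (1.665 ± 0.60, 0.106), Smarcb1 (0.92 ± 0.615, 0.38), Hmga2 (1.34 ± 1.18, 0.518), Igf2bp1 (1.61 ± 1.615, 0.577), Mycn (-0.82 ± 0.66, 0.475) and Gli2 (-2.86 ± 1.38, 0.212) did not pass. Alternatives called Cdkn2a, Mcm3 and Adgre1 (DESeq2, 0.0114 to 0.0441), Mcm3, Adgre1 and Igf2bp1 (limma voom, 0.00577 to 0.0418), Adgre1 (without Extracranial tumor 1, 0.0329) and Igf2bp1 (5.935, without Extracranial tumor 3, 0.0464).

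edgeR called 465 genes higher and 563 lower, DESeq2 1478 and 2188, and limma voom 1640 and 1255, which turned the balance (56.6% higher against 45.2%). With the compared groups only the counts were 71 and 39, and with 1 library left out 44 to 854 and 10 to 1116, with the fewest higher without graft 2. Of the 23 calls named here those of Gli1, Pcsk1n, Acot5, Ifng and Pdcd1lg2 were kept without each library. With the compared groups only, 16 of the 23 were lost (adjusted p from 0.0625 to 0.15), among them Acot5 (0.0776), Ifng (0.0794) and Pdcd1lg2 (0.0732), and with sex as a covariate 7 (0.0506 to 0.0673). Without Syngeneic graft 1, 2 and 3, 17, 17 and 16 calls were lost (adjusted p up to 0.148, 0.137 and 0.135), and without Extracranial tumor 2, 3 and 4, 7, 1 and 3 (up to 0.0716, 0.0725 and 0.0791). Of the list calls, those of Myc targets (fry adjusted p = 0.336), the cell cycle (0.052), matrix genes (0.126) and skeletal muscle (0.0997) did not pass with fry. Lost were matrix genes without Extracranial tumor 2 (0.103), Hedgehog without Extracranial tumor 3 (0.0522) and Myc targets without Extracranial tumor 1 (0.292) or 2 (0.251). Imprinted and fetal genes were lost with RLE factors (0.0534) and without Extracranial tumor 1 (0.111), Extracranial tumor 4 (0.0891) or Syngeneic graft 3 (0.0513).

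Syngeneic grafts (n = 3) were compared with Myc tumors (n = 4). As lists, T and NK cells (8 of 22 genes called), macrophages (4 of 22) and MHC class I and II (6 of 14 and 3 of 8) were higher in the grafts, which did not pass with an estimated correlation (adjusted p = 0.143 to 0.147). Gfap, Aqp4, Gli1 and Sox2 were lower. Cd4 averaged 40.8 ± 8.54 CPM in grafts and 3.58 ± 1.63 in Myc tumors (3.51 ± 0.54, edgeR adjusted p = 0.0089), and Psmb8 223 ± 22.5 and 66.3 ± 11.9 (1.75 ± 0.27, adjusted p = 0.0089). Pla2g2d, a phospholipase gene of myeloid cells, averaged 70.4 ± 39.1 and 0.0796 ± 0.0754 CPM (9.81 ± 1.26, adjusted p = 0.00686). Pdcd1lg2 rose by 6.615 ± 0.965 (adjusted p = 0.00871).

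T and NK cells (8 of 22 genes rose, camera adjusted p = 3.59e-20), macrophages (4 of 22, 3.31e-11), MHC class I (6 of 14, 1.45e-09), MHC class II (3 of 8, 1.24e-08), immune checkpoints (3 of 10, 0.000551) and the interferon response (4 of 31, 1.42e-08) were higher as lists. The cell cycle (2 of 35, adjusted p = 8.7e-12), endothelium (1 of 13, 0.000892), Hox genes (36 not passing, 0.000263) and erythroid cells (7 not passing, 0.00165) were higher too. For T and NK cells and checkpoints adjusted p = 0.143 with an estimated correlation, for macrophages and MHC class I and II 0.147 and for the others 0.459. Astrocytes (3 of 12 fell, adjusted p = 0.00677), neurons (2 of 20, 0.0163), the Hedgehog pathway (3 of 18, 0.0165), keratinocytes (1 of 9, 0.00522) and oligodendrocytes (1 of 12, 0.0415) were lower. So were mitochondrially encoded genes (13 not passing, adjusted p = 0.0196) and Schwann cells (8 not passing, 0.0277). The lower lists had, with an estimated correlation, adjusted p = 0.143 (keratinocytes), 0.459 (Hedgehog, Schwann cells), 0.576 (astrocytes), 0.637 (neurons), 0.653 (mitochondrial) and 0.74 (oligodendrocytes). Adjusted over the list alone, 19 T and NK cell, 18 cell cycle, 11 MHC class I, 11 interferon, 7 MHC class II and 3 erythroid genes rose. On the same basis 15 macrophage genes rose and 1 fell, 7 checkpoint genes rose and 1 fell, 6 endothelial genes rose and 1 fell, and 6 astrocyte, 5 oligodendrocyte, 5 keratinocyte, 3 neuron, 3 Hedgehog and 3 Schwann cell genes fell.

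Ifng averaged 0.6235 ± 0.301 CPM in grafts and 0.0380 ± 0.0257 in Myc tumors (3.83 ± 0.66). The checkpoint genes Lag3 and Tigit rose by 2.63 ± 0.58 and 4.105 ± 0.96, Tap1 and Ciita by 1.53 ± 0.29 and 3.71 ± 0.95 and Cxcl9 by 6.21 ± 1.73. The macrophage genes Adgre1, Arg1 and Retnla rose by 2.61 ± 0.62, 4.17 ± 0.99 and 10.04 ± 1.89. Cenpa, a centromere protein gene, and Pcna rose by 1.61 ± 0.39 and 0.998 ± 0.26, and Cdh5 by 1.83 ± 0.46. Gfap and Aqp4 fell by 7.83 ± 1.63 and 10.53 ± 2.595, Sox2 by 7.30 ± 1.425, and Gli1 and Sfrp1 by 4.47 ± 0.96 and 3.59 ± 0.69. Col5a2 (-3.95 ± 0.85) and, among the largest decreases, the retinoic acid-binding protein gene Crabp1 (-12.38 ± 2.90) and the prostaglandin receptor gene Ptgfr (-10.42 ± 1.695) fell. Smarcb1 (1.47 ± 0.62, adjusted p = 0.155, but 0.0105 with limma voom and 0.0276 with the compared groups only), Mycn (1.33 ± 0.67, 0.234), Cdkn2a (0.295 ± 0.39, 0.684), Myc (0.14 ± 0.35, 0.852), Igf2bp1 (0.05 ± 1.61, 0.997), Ptch1 (-0.31 ± 0.49, 0.742), Hmga2 (-0.63 ± 1.20, 0.793) and Gli2 (-0.95 ± 1.28, 0.693) did not pass.

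edgeR called 670 genes higher and 620 lower, limma voom 2129 and 1948, and DESeq2 1496 and 2181, which turned the balance (40.7% higher against 51.9%). With 1 library left out the counts were 46 to 588 and 12 to 781, both lowest without graft 2. Of the 24 calls named here those of Cd4, Psmb8, Pla2g2d and Pdcd1lg2 were kept without each library. With the compared groups only, 5 of the 24 were lost (adjusted p from 0.0539 to 0.0702), with sex as a covariate Pcna (0.05) and Cxcl9 (0.0663) and with limma voom Arg1 (0.0681). Without Syngeneic graft 1, 2 and 3, 17, 20 and 18 calls were lost (adjusted p up to 0.13, 0.187 and 0.127), and without Myc CNS tumor 1, 2, 3 and 4, 5, 5, 8 and 9 (up to 0.0683, 0.0874, 0.0969 and 0.0875). With fry the lists of the cell cycle (adjusted p = 0.0574), Hox genes (0.0973), interferon (0.082), endothelium (0.0703), Hedgehog (0.082), neurons (0.247), oligodendrocytes (0.388), astrocytes (0.189), Schwann cells (0.0973) and mitochondrial genes (0.224) did not pass. Lost were astrocytes without Myc CNS tumor 4 (0.0515), Hedgehog without Syngeneic graft 2 (0.0636), neurons without Myc CNS tumor 4 (0.0683), mitochondrial genes without Myc CNS tumor 1 (0.0529) or 4 (0.0683) and Schwann cells without Syngeneic graft 2 (0.0778) or Myc CNS tumor 1 (0.134). Oligodendrocytes were lost without Myc CNS tumor 1, 3 or 4 or any graft (0.0529 to 0.265).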

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

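All 6 tests of explanations in this part were chosen after the results were seen, and the 9 tests with other splits of the libraries were fixed before.

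In groups of 4 libraries, 9 values of genes and lists lay far from the other 3 libraries, measured as the gap to the nearest library over the whole range of the group, tested at the 95% level of Dixon's test. There were 211 such groups, and chance gives about 1 in 20. In Myc tumors the neuron markers of Myc CNS tumor 2 lay below the others (gap 0.925, mean log2(CPM + 1) 2.23 against 4.17 to 4.33). The skeletal muscle markers (0.883, 2.88 against 0.51 to 0.79) and Lyz2 (0.893, 11.21 against 9.21 to 9.43) of Myc CNS tumor 1 lay above, as did Bst2 of Myc CNS tumor 3 (0.905, 8.91 against 7.86 to 7.96). In extracranial tumors the astrocyte markers of tumor 3 lay above the others (0.896, 2.49 against 1.57 to 1.67). Col5a2 of tumor 1 (0.85, 8.47 against 11.21 to 11.7), Fbln2 of tumor 3 (0.851, 4.52 against 10.15 to 11.14), and the Schwann cell markers (0.878, 0.9 against 1.15 to 1.19) and Hoxc9 (0.864, 1.1 against 4.18 to 4.66) of tumor 2 lay below.

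Of the fixed genes, 2 were called in opposite directions against brain, with a called difference between the tumor groups. Ptch1 rose in SHH tumors (2.129) and fell in Myc tumors (-1.55), and the difference of Myc from SHH tumors was -3.679. The rise was lost in several alternatives (adjusted p = 0.085 to 0.169 without each single brain, 0.086 with sex as a covariate) and the fall without Healthy brain 1 (0.0507). Gli1 rose in extracranial tumors (2.252) and fell in grafts (-5.855), and the difference of grafts from extracranial tumors was -8.106. The rise was lost without Healthy brain 2 or 3 or Extracranial tumor 1 or 3 (0.0608 to 0.124).

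Counts of Smarcb1 in tumors labelled null were weighed against cells with an intact gene in the samples and against reads of other loci. Over the 8 Myc and extracranial tumors, the correlation of Smarcb1 with the macrophage list was r = 0.401 (exact p = 0.324) and -0.592 without the 2 libraries farthest from the median macrophage score (Extracranial tumor 1 and Myc CNS tumor 1), which leaves the admixture of other cells undecided. Of 18 cell type lists neutrophils (-0.657) and skeletal muscle (0.635) had the largest r, and none passed (adjusted p of at least 0.83). Outside these 8 tumors some values went with admixture: SHH CNS tumor 1, with 4017 CPM of Mbp, had the most Smarcb1 of the tumors (33.25 CPM), and the grafts, 2 of them with Xist and Y transcripts together, held 29.0 ± 3.35 CPM. Reads of other loci at one level in every library could not give the spread, since the lowest tumor held 0.192 of the median of the 14 (2.515 against 13.08 CPM). Transcripts from a gene with a deleted part were not tested, since the counts cover the whole gene.

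Syngeneic graft 1 and 2 held both Xist (541.9 and 801.8 CPM) and transcripts of the Y chromosome (122.7 and 96.18 CPM summed), whereas graft 3 held Xist (1107 CPM) and 0.0313 CPM of Ddx3y. A mixture of XX and XY cells predicts Xist and Y shares that add up to 1, and the sums were 0.907 (0.428 and 0.479) and 1.009 (0.634 and 0.375). Libraries without Y transcripts held 700.2 to 2507 CPM of Xist, so the sums cannot decide. RNA carried over from a library with Y transcripts was excluded, since transcripts of the 5 sources reached at most 0.00411 of the level needed. The labels give no sex of tumor or host.

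The 3 brains held transcripts of brain development and little of mature brain, and the labels read here give no age. A mature stage was excluded, since the oligodendrocyte markers, a list fixed before, had mean log2(CPM + 1) of 2.166 to 2.365 in the brains against 7.648 in SHH CNS tumor 1, a tumor with myelin transcripts (highest brain minus that tumor -5.283). The stage of the brains stays open. The tests of stage and muscle replaced earlier ones on the ratio of early to late genes, which was above 1 in all 17 libraries and so could not decide. Muscle in the dissection was excluded as the source of the early transcripts, since Healthy brain 2 and 3, with low muscle scores (0.673 and 0.668, against 3.453 in Healthy brain 1), held at least 0.962 of the early median of Healthy brain 1 (429.5 and 380.6 against 395.8 CPM).

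Other splits of the libraries into groups of the same sizes were run for each comparison, and the number of splits that called as many genes as the real one is given with the real one included. The median over the other splits was 0 genes in each comparison. For tumors and brain this was 1 of 100 splits (11473 genes, at most 6528 in another split), for Myc tumors and brain 1 of 35 (11216, 5404), for extracranial tumors and brain 1 of 35 (11230, 6322), for Myc and SHH tumors 1 of 35 (8789, 3307) and for grafts and Myc tumors 1 of 35 (1290, 527). The highest other split kept the 3 brains as brain for all tumors, and in the other 4 comparisons set the whole group of 3 with 1 library of the other group against the rest, so these splits held most of the real contrast. For SHH tumors and brain (1 of 10, 940 genes, at most 1 in another split) and grafts and brain (1 of 10, 11891, 0) the splits are too few to exclude chance. For extracranial and Myc tumors it was 9 of 35 (4 genes, up to 39 in another split) and for grafts and extracranial tumors 2 of 35 (1028, up to 1370), so chance was not excluded for either. The split with 1370 genes set Extracranial tumor 2, 3 and 4 against Extracranial tumor 1 and the 3 grafts.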

How the results depend on the processing

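The alternatives were fixed before the data were seen, except the one without both Healthy brain 1 and SHH CNS tumor 1. Of 304 counts of called genes under an alternative, 225 stayed within 1.5 times the value reported and 79 did not. For 286 results of named genes, which include results that did not pass, 3831 of 4246 alternatives left the outcome, called or not, as it was, 368 lost a call, 44 gained one and 3 reversed, and for the lists 1594 of 1883 kept it, 289 lost it (155 of them with an estimated correlation) and 0 reversed. DESeq2 gave no adjusted p for 16 gene values. In simulated counts 34% of 4-fold and 80% of 16-fold changes between SHH tumors and brain were recovered, 38% and 86% between extracranial and Myc tumors, 32% and 86% between grafts and extracranial tumors and 40% and 74% between Myc tumors and brain. Where a cause is not named, the cause was not tested.

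Counts are given as genes higher and lower. RLE size factors gave 10 lower between extracranial and Myc tumors. With every gene with a count, SHH tumors against brain gave 319 and 266, grafts against extracranial tumors 296 and 218 and grafts against Myc tumors 343 lower. With sex as a covariate SHH tumors against brain gave 281 and 233, extracranial against Myc tumors 1 higher and grafts against extracranial tumors 259 and 251. DESeq2 gave 1560 and 1268 for SHH tumors against brain, 478 and 745 for extracranial against Myc tumors, 1478 and 2188 for grafts against extracranial tumors and 1496 and 2181 for grafts against Myc tumors. In the last of these the share of higher genes was 40.7% against 51.9%, and between extracranial and Myc tumors 39.1% against 0%. Limma voom with quality weights gave 3274 and 4285 for SHH tumors against brain (43.3% higher, against 55.7%), 0 lower for extracranial against Myc tumors, 1640 and 1255 for grafts against extracranial tumors (56.6%, against 45.2%) and 2129 and 1948 for grafts against Myc tumors. It reversed Smarcb1 (1.364, adjusted p = 0.0453) and Mobp (0.376, adjusted p = 0.89) between Myc and SHH tumors. With the 14 tumors as 1 group 3604 genes were higher and 2848 lower than in brain. With the compared groups only, a fit on fewer libraries, 0 genes were lower between extracranial and Myc tumors, and grafts against extracranial tumors gave 71 and 39. With only libraries whose file numbers lay in the same series, Myc against SHH tumors gave 2047 and 2619 and extracranial against Myc tumors 8 lower. Without Healthy brain 1 and SHH CNS tumor 1, SHH tumors against brain gave 304 and 170.

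With 1 library left out, SHH tumors against brain ranged from 27 to 513 higher and 35 to 308 lower, extracranial against Myc tumors from 0 to 23 and 0 to 71, grafts against extracranial tumors from 44 to 854 and 10 to 1116 and grafts against Myc tumors from 46 to 588 and 12 to 781. Igf2bp1 in extracranial tumors against brain ranged from -3.823 (adjusted p = 0.0403, without Extracranial tumor 3) to 1.094. A minimum count of 50 kept each count within 1.5 times.

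The library number as a replicate block gave 0 genes lower between extracranial and Myc tumors, 269 and 161 for grafts against extracranial tumors and 349 and 229 for grafts against Myc tumors. Of the calls named, it lost 4 of 4, 5 of 23 and 11 of 24 in these comparisons, 7 of 27 between SHH tumors and brain (Ptch1 0.0511 to Mobp 0.114), 3 of 35 between Myc and SHH tumors (Psg22 0.104 to Mobp 0.181) and Psg22 (0.0712) between Myc tumors and brain. The numbers did not pair the libraries: over 31 pairs with the same number the deviations from the group means had a median r of 0.014 (-0.167 to 0.166, 2 pairs over 0.1), other pairs -0.0045, and 6 of 17 libraries correlated best with their own number.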

Other observations

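No test in this part was run, and the genes were chosen after their values were seen.

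The pituitary hormone genes Gh and Pomc were highest in 2 libraries. Healthy brain 1 held 1215 CPM of the growth hormone gene Gh, 142.6 of Pomc and 6.082 of Cga, against at most 0.1352, 0.7958 and 0.0097 in the other brains, but 0.3811 of the prolactin gene Prl. Myc CNS tumor 1 held 71.4 CPM of Gh, 56.14 of Prl and 64.29 of Pomc, against at most 0.5325, 0.0698 and 0.7071 in the other Myc tumors. SHH CNS tumor 3 held 2.491 CPM of Prl (220 counts) and 1.076 of Gh (95 counts), with no counts of either in SHH CNS tumor 1 and 2. The choroid plexus gene Ttr was at 709.2, 347.8 and 0.9385 CPM in Healthy brain 1, 2 and 3 and at 1679 CPM in SHH CNS tumor 1, against 1.199 and 0.8038 in SHH CNS tumor 2 and 3.

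Tumors of one group also differed in the collagen gene Col1a1, which was at 231.4, 296.8, 11.34 and 5548 CPM in Myc CNS tumor 1, 2, 3 and 4 and at 265, 466, 1831 and 2612 CPM in Extracranial tumor 1, 2, 3 and 4. Psg22 and Gata4 were at 1.367 and 2.241 CPM in Myc CNS tumor 1, 245.3 and 41.72 in tumor 2, 0.0611 and 0.6984 in tumor 3 and 157.9 and 209.5 in tumor 4.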
